A study of Homo sapiens with 18 samples.

How the data were processed

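Expression was measured with 18 Affymetrix arrays of 54675 probe sets in CD34+ cells from adult peripheral blood, cultured toward red cells for 11 days. RNA was taken with a Qiagen micro kit, and 50 ng of it was amplified and labelled with the Ovation biotin system, per the labels. The deposited values are intensity on a linear scale, made by the authors in GCOS 3.0 per the submitters' processing notes, and each array's 2% trimmed mean lay at 500.1 in the table. Further settings of that step are not given in the sources used here. Detection calls and the unprocessed array images were not used here.

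Groups were the days given in the titles: 1, 3, 5, 7, 9 and 11, with 3 arrays each and 2 on day 3. The remaining array has "Culture 3, biological replicate 3" in its title in place of a day and was left out of every comparison. Culture 3 stands there where the other titles give the day, so that title does not show what the replicate numbers mean. The titles of the other arrays name no culture, and none states outright that the numbers pair arrays across days. The number was therefore not used as a block in the main model, and a block was tried as an alternative. No pair of the 18 arrays shared over 50% of its values.

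Of the probe sets, 62 controls, 1801 with several gene symbols and 11721 with none were left out. The remaining 41091 have 1 symbol, and 41037 of them were matched to a gene table by Entrez ID, with 0 symbols changed, which gave 19740 genes. Genes measured only by probe sets shared between genes, such as the alpha and gamma globins, were not analysed here, nor were Y-linked genes and XIST named. Each gene was represented by the probe set with the highest mean over the 17 arrays. Signals were taken as log2(signal + 3.9), where 3.9 is the 10th percentile of all values, without further scaling. A gene was tested if it lay above the array's median in at least 2 of 17 arrays, which left 15619 genes.

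A linear model with a mean for each day was fitted to all 17 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend), with 11 residual and 12.8 prior degrees of freedom. Comparisons were day 11 against day 1, each step between neighbouring days, the mean of days 5 and 7 against both ends, and an F test over the 6 days. Benjamini-Hochberg adjusted p was taken over all genes of a comparison, at 0.05. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

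Gene lists were written by hand before the data were examined, as were the design, the alternatives and the rule for naming genes. The 26 lists are globins and the alpha globin chaperone, haem synthesis, iron uptake and handling, red cell membrane and skeleton, erythroid transcription factors and cofactors, late erythroid maturation, stem and progenitor cell, granulocyte and monocyte, mast cell with basophil and eosinophil, megakaryocyte and platelet, lymphoid, macrophage and antigen presentation, DNA replication and G1/S, mitosis and G2/M, cyclin D with CDK inhibitors and the MYC network, nucleolus and ribosome biogenesis, cytosolic ribosomal proteins, glycolysis, TCA cycle and oxidative phosphorylation, cholesterol synthesis, antioxidant and glutathione, erythropoietin and cytokine signalling, glucocorticoid induced, immediate early and stress, interferon response, and heat shock and unfolded protein. Lists were tested with camera at a preset correlation of 0.01, adjusted over 156 tests (26 lists in 6 comparisons), and again with a correlation estimated from the data. The preset gave 91 calls and the estimate 26. By comparison (day 11 against day 1, then the steps in order) these were 17, 15, 14, 11, 17 and 17 with the preset and 7, 6, 3, 5, 4 and 1 with the estimate.

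Genes were named by a rule: a fixed set of known red cell and progenitor genes, the 8 largest rises and falls among called genes for day 11 against day 1 and the 5 largest each way for each step, with arrays of the 2 days not overlapping, the 5 with the largest smaller difference each way for the middle days, and up to 4 called and 2 uncalled members of each list. Unnamed reading frames, HLA class I, immunoglobulin and T cell receptor genes were passed over. The text names a selection of these. A change is given as a bound, or with one, when all arrays of the dimmer day (or of days 5 and 7 together) lay below their own median. Where only some of them did, the text gives the number above it for called genes. Of 7936 tested genes with more than 1 probe set past the filter, 2570 were called for day 11 against day 1, and for 18 of these another probe set was called the opposite way.

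The test was tried on simulated data with 200 of 15619 genes changed 2-, 4- or 8-fold. It recovered 34.3%, 74.6% and 87.9% for day 11 against day 1, 20.9%, 61.2% and 78.8% for day 3 against day 1, 26.9%, 67.2% and 86.4% for day 5 against day 3, 31.3%, 71.6% and 86.4% for day 7 against day 5, 19.4%, 70.1% and 89.4% for day 9 against day 7, and 26.9%, 71.6% and 84.8% for day 11 against day 9. False calls numbered 5, 8, 4, 7, 6 and 7 in the same order. With no gene changed it made 0 calls. The simulated noise was normal and independent between genes and arrays, and the dimmest genes were not changed. Array-wide differences and correlated genes were thus not part of it, so these rates may not hold for the real arrays.

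The alternatives were quantile normalization, equal medians, a pseudocount 4 times lower or higher, no filter and a filter at the 75th percentile, the mean of a gene's probe sets, eBayes without trend and with robust fitting, a replicate block, the 3' to 5' ratio as a covariate, only the 2 days compared in the fit, the estimated correlation, and leaving out each array. Chosen after seeing the data were 16 times the pseudocount and leaving out both doubted arrays together.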

Results

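Messenger RNA of human CD34+ progenitor cells from adult peripheral blood was measured while the cells were led toward red cells in culture over 11 days, on 18 microarrays with 54675 probe sets each. The serum-free medium held erythropoietin at 4 units/ml, stem cell factor and interleukin 3 at 10 ng/ml each, dexamethasone at 1 µM and holo transferrin at 0.3 mg/ml, per the labels. The titles give 3 biological replicates on each of days 1, 5, 7, 9 and 11 and 2 on day 3. On 1 further array the title gives no day, and it stands in no comparison. The number of arrays limits the precision of every value. Signals are on a linear scale, with the 2% trimmed mean of each array at 500.1. Fold changes are on the log2(signal + 3.9) scale, where the added 3.9 makes the change of low genes smaller. Folds of genes dim on 1 of the days are still no lower limits. With dim arrays raised to their median, that of SLC4A1 for day 11 against day 1 went from 526 to 264. The titles call the samples biological replicates without saying whether they come from separate donors, so p-values measure the spread between these samples only. Array quality differed in 2 places. The mean log2 ratio of 3' to 5' control probe sets was 7.14 on day 3 replicate 3 and 1.59 to 4.28 on the others. The median signal was 96.3 on day 11 replicate 1 and 37.5 to 72.7 on the others.

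The study was designed to describe the transcriptome of developing red cells at 6 times. The main red cell products rose in an order. HBB, the beta chain of adult haemoglobin, had a signal of 5138 ± 1690 (SD, n = 3) on day 1, 16620 ± 3128 (n = 2) on day 3 and 37120 ± 3544 (n = 3) on day 11. AHSP, the chaperone of free alpha globin, went from 106.5 ± 87.6 on day 1 to 2044 ± 956 on day 3 and 14480 ± 2279 on day 7. ALAS2, which starts haem synthesis in red cell precursors, and SLC4A1, the band 3 anion exchanger, were at 542 ± 275 and 1079 ± 408 on day 5 and at 11100 ± 439 and 20040 ± 783 on day 9. The progenitor surface proteins PROM1 (CD133) and CD34 stood at 5209 ± 1177 and 1539 ± 286 on day 1 and at 67.6 ± 2.75 and 33.6 ± 39.2 on day 5. GATA2, a transcription factor of progenitors, went from 11710 ± 2441 on day 1 to 918 ± 151 on day 7. GATA1, which replaces it in red cell precursors, went from 579 ± 194 on day 1 to 1819 ± 296 on day 9. Between any of the 6 days, 5575 of 15619 genes tested differed (limma moderated F test, Benjamini-Hochberg adjusted p below 0.05). Of these, 39% had their highest mean on day 1 and 21.5% on day 9. The lowest mean lay on day 9 for 34.5% of them. The leading principal component held 31.1% of the variance and placed the arrays from -115.58 to -104.21 on day 1 and from 67.21 to 88.16 on day 9. Day 11 lay back at 40.59 to 52.43.

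**Figure D1:**
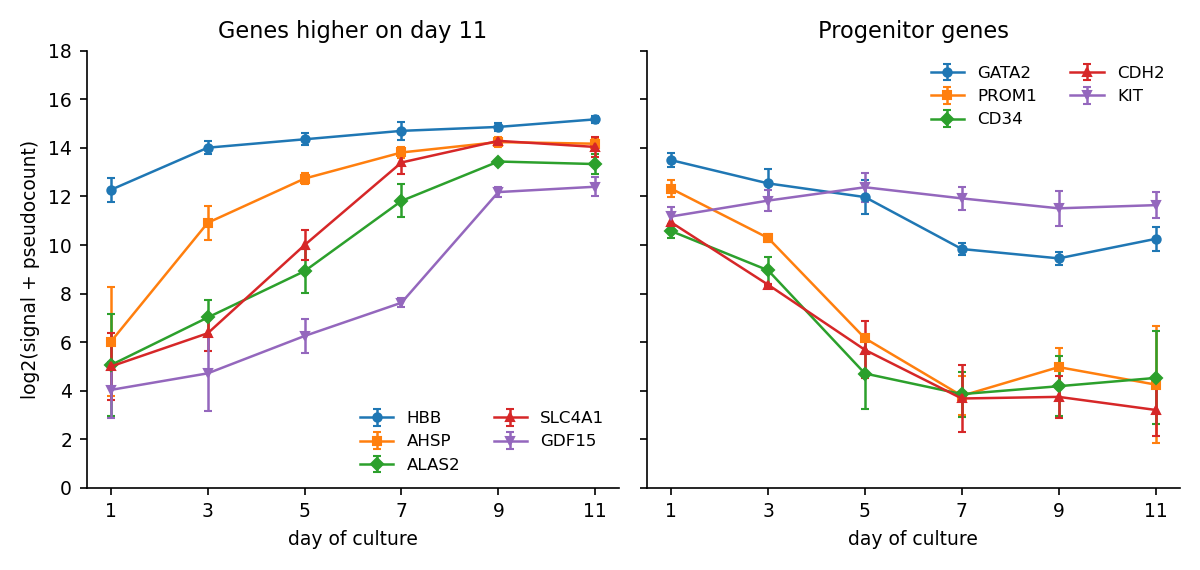
Level of 10 genes on a log2(signal + pseudocount) scale against the day of culture, as mean and SD over the arrays of each day (n = 3, and 2 on day 3). HBB is high from day 1 on, AHSP, SLC4A1, ALAS2 and GDF15 climb at different days, and PROM1, CD34 and CDH2 are near their lowest level by day 7 while KIT stays high.

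The comparison of day 11 with day 1 asks what the whole culture changed. SLC4A1 rose by 9.04 ± 0.45 on the log2 scale (526-fold, SE, adjusted p = 4.81e-13), ALAS2 by 8.28 ± 0.62 (310-fold, adjusted p = 4.83e-10) and AHSP by 8.15 ± 0.58 (284-fold, adjusted p = 1.69e-10). Where all arrays of the dimmer day lay below their own median, the change is given as a bound, with each array's dim signal raised to that array's median. On that basis GDF15, a secreted factor of the TGF-beta family, rose at least 85.6-fold, TLCD4 at least 118-fold, PLEK2, a pleckstrin of red cell precursors, at least 60.1-fold, SOX6, a transcription factor of definitive red cells, at least 49.5-fold, and PAQR9 at least 45.4-fold (adjusted p from 8.02e-17 to 1.43e-07). PROM1 fell by 8.07 ± 0.77 on the log2 scale (269-fold, adjusted p = 2.68e-08) and TM4SF1, a membrane protein, fell by 6.21 ± 1.03 (74-fold, adjusted p = 6.55e-05). CDH2 (N-cadherin) fell at least 29-fold, HLA-DQA1 of the class II complex at least 81.4-fold, the B cell marker MS4A1 at least 25.1-fold, the decoy receptor IL1R2 at least 17.8-fold, the cytokine receptor IL27RA at least 18.5-fold and RGS1, a regulator of G protein signalling, at least 38.5-fold (adjusted p from 7.16e-08 to 2.37e-05). Of the genes with an exact fold, 1 of 3 arrays of day 1 lay above its median for SLC4A1 and ALAS2 and 2 of 3 for AHSP, and 1 of 3 arrays of day 11 for PROM1 and 2 of 3 for TM4SF1. With the other arrays of that day raised to their median, the folds are 264, 128, 158, 71 and 35.3 in this order. For each gene of this paragraph the 3 arrays of day 11 all lay beyond the 3 of day 1, as the rule for naming required. In all, 1602 genes were higher and 2595 lower on day 11, of which 1146 and 2054 changed at least 2-fold.

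Of the genes followed throughout, HBB rose by 2.90 ± 0.21 on the log2 scale (7.48-fold) and EPOR, the erythropoietin receptor, by 2.93 ± 0.17. BNIP3L, which clears mitochondria, rose by 2.43 ± 0.22, the fatty acid receptor CD36 by 2.23 ± 0.21, the proliferation marker MKI67 by 2.22 ± 0.27, the erythroid factor KLF1 by 1.74 ± 0.21 and the transferrin receptor TFRC by 0.82 ± 0.17 (adjusted p from 9.22e-12 to 0.000626). GATA2 fell by 3.24 ± 0.31 and CD34 by 6.05 ± 0.87 (adjusted p = 2.13e-08 and 1.12e-05). On day 11, 1 of 3 arrays lay above its median for CD34. GATA1 rose by 0.86 ± 0.26 (adjusted p = 0.0171) and BCL11A, a repressor of fetal globin, by 0.74 ± 0.25 (adjusted p = 0.0289). Neither call was firm: without day 1 replicate 1 GATA1 stood at 0.59 (adjusted p = 0.121), and without day 11 replicate 1 BCL11A stood at 0.67 (adjusted p = 0.0996). KIT (0.47 ± 0.34, adjusted p = 0.346), MYB (-0.14 ± 0.18, adjusted p = 0.633) and MYC (0.20 ± 0.36, adjusted p = 0.739), which mark proliferating progenitors, did not pass the test.

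The red cell lists moved almost as blocks between day 1 and day 11. Of 14 measured genes of haem synthesis 13 rose (13 adjusted over the list alone), among them FAM210B (3.58), PPOX (3.39) and FECH (2.94), which inserts the iron. The housekeeping enzyme ALAS1 stood at -0.66. In the red cell membrane and skeleton list 20 of 24 rose (20 adjusted over the list alone, with 1 lower), led after SLC4A1 by the water channel AQP1 (6.97), EPB42 (6.78) and ADD2 (6.55). CD47 stood at -0.11 and PIEZO1 at -0.66. Late maturation genes rose in 26 of 27 cases (26 adjusted over the list alone), with TRIM10 (6.16), SELENBP1 (6.05), OSBP2 (5.35) and the carbonic anhydrase CA1 (5.11) in front and the ubiquitin ligase UBE2O at -0.46. Of 21 erythroid transcription factors and cofactors 17 rose and 1 fell (the same numbers adjusted over the list alone). NFIA (3.24), KLF3 (2.72) and E2F2 (2.19) came after SOX6, and TRIM28 (-0.86) was lower. Globins and the alpha globin chaperone gave 5 of 7 higher (5 adjusted over the list alone). After AHSP came HBM (6.58, at least 61.9-fold), HBB, HBQ1 (2.63) and HBD (1.40). The embryonic HBE1 (1.44) and HBZ (1.83, and 1.12-fold with the dim arrays of day 1 raised to their median) did not pass. The list tests gave adjusted p = 5.6e-17, 7.2e-22, 2.61e-30, 2.78e-12 and 2.65e-09 in this order, and 0.00179, 0.00232, 0.00179, 0.0175 and 0.0111 with an estimated correlation. Iron uptake and handling rose less, by a mean of 0.67, with 10 of 15 higher and 2 lower (12 and 2 adjusted over the list alone). Called were the endosomal iron reductase STEAP3 (1.53) and the mitochondrial iron importer SLC25A37 (1.48), and the haem exporter FLVCR1 lower (-1.40). Its adjusted p was 1.25e-05, and 0.0583 with an estimated correlation. TRIM28 lost its call without day 11 replicate 1 (-0.60, adjusted p = 0.0818). On day 1, 1 of 3 arrays lay above its median for AQP1, ADD2, SELENBP1 and OSBP2 and 2 of 3 for EPB42. With the other arrays of day 1 raised to their median, AQP1 rose 44.3-fold, EPB42 83.6-fold and ADD2 50.7-fold, which changes their order. SELENBP1 then rose 39.1-fold and OSBP2 22.4-fold, the latter less than CA1 (34.6-fold).

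Genes of mitosis were higher on day 11 than on day 1. Of 29 genes of mitosis and G2/M 28 rose (29 adjusted over the list alone), such as the spindle proteins DLGAP5 (2.82), KIF20A (2.82) and CENPE (2.64), with KIF2C at 0.65. The mitosis list had adjusted p = 3.32e-25, and 0.0103 with an estimated correlation. The DNA replication and G1/S list did not move with it. In it 3 of 28 were higher, among them RFC5 (1.04), and 2 lower, MCM3 (-0.97) and GINS2 (-0.92), also adjusted over the list alone. Its mean was -0.05 against an upward sign of the test (adjusted p = 0.69). MCM3 lost its call without day 11 replicate 1 (-0.89, adjusted p = 0.0529). Cyclin D, CDK inhibitors and the MYC network gave 6 higher and 2 lower of 23 (8 and 3 adjusted over the list alone, adjusted p = 0.0659). MYCN (-5.60) and CDK6 (-1.48) were down and the inhibitors CDKN2A (3.17, at least 2.57-fold) and CDKN1B (1.76) and the stress gene GADD45A (2.02) were up. Nucleolus and ribosome biogenesis fell in 10 of 27 genes (10 adjusted over the list alone, adjusted p = 0.00255, and 0.358 with an estimated correlation). RRP9 (-1.76), NOP2 (-1.69) and NHP2 (-1.29) were lower, and NPM1 stood at -0.10. RRP9 lost its call without day 11 replicate 1 (-1.25, adjusted p = 0.0552). Of 27 cytosolic ribosomal protein genes 0 were called by limma in either direction or adjusted over the list alone, with a mean of 0.14 (list adjusted p = 0.0488, and 0.716 with an estimated correlation). On day 11, 1 of 3 arrays lay above its median for MYCN and 2 of 3 for RRP9. The ribosomal protein mean turned to -0.035 under quantile normalization, and the list lost its call without any 1 of 9 arrays, as without day 1 replicate 1 (0.10, adjusted p = 0.118).

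Progenitor and other lineage genes went down in most lists from day 1 to day 11. Of 25 stem and progenitor genes 17 fell (17 adjusted over the list alone): beside PROM1 and CD34 these were SPINK2 (-6.05, at least 20.3-fold) and the transcription factor HLF (-5.18). MYB and the sialomucin CD164 (-0.03) did not pass (list adjusted p = 5.67e-08, and 0.0215 with an estimated correlation). The macrophage and antigen presentation list had 8 of 15 lower and 1 higher (the same adjusted over the list alone). In front were the class II complex genes HLA-DRA (-5.36), CD74 (-5.32) and HLA-DPA1 (-4.64) and the scavenger receptor CD163 (-4.76) (list adjusted p = 0.000149, and 0.0855 with an estimated correlation). Lymphoid genes gave 8 of 17 lower (8 adjusted over the list alone), among them IL32 (-5.62, at least 7.24-fold), PRF1 (-4.91) and IL7R (-3.51), with adjusted p = 0.00193, and 0.176 with an estimated correlation. In the mast cell, basophil and eosinophil list 8 of 15 were lower and 2 higher (8 and 3 adjusted over the list alone). The mast cell tryptases TPSAB1 (-4.75) and TPSB2 (-4.37) and the histamine enzyme HDC (-4.52) fell, and eosinophil peroxidase EPX rose (3.98, at least 5.16-fold). This list's adjusted p of 0.0404 became 0.344 with an estimated correlation and rose above 0.05 without any 1 of 5 arrays, at most without day 11 replicate 1 (mean -0.53, adjusted p = 0.0864). So did that of EPX without day 11 replicate 3 (2.91, adjusted p = 0.0855). Granulocyte and monocyte genes gave 7 lower and 3 higher of 24 (the same adjusted over the list alone, list adjusted p = 0.442). Lower were VCAN (-4.16, at least 10.8-fold), the transcription factors SPI1 (-3.53) and CEBPA (-2.65) and S100A8 (-3.39). S100A8 lost its call without day 1 replicate 2 (-2.57, adjusted p = 0.0789). Megakaryocyte and platelet genes went the other way, with 10 of 19 higher and 4 lower (10 and 5 adjusted over the list alone). CLEC1B (4.73), the platelet chemokines PPBP (4.66) and PF4 (4.04) and LTBP1 (4.38) rose and VWF (-3.14, at least 3.38-fold) fell (list adjusted p = 0.00589, and 0.295 with an estimated correlation). Of day 11, 1 of 3 arrays lay above its median for HLF, CD163, PRF1, SPI1 and CEBPA and 2 of 3 for HLA-DRA, TPSAB1, TPSB2, HDC and S100A8, and of day 1, 1 of 3 for CLEC1B. With the other arrays of day 11 raised to their median, HLF fell 9.18-fold, CD163 20.7-fold, PRF1 9.48-fold, SPI1 3.03-fold and CEBPA 3.78-fold.

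Metabolic lists fell or split between day 1 and day 11. Glycolysis fell in 10 of 20 genes and rose in 3 (14 and 3 adjusted over the list alone). PKM (-3.17), ENO1 (-2.34) and PFKP (-2.06) were lower. The red cell pyruvate kinase PKLR (1.49), PFKM (1.43) and hexokinase HK1 (1.34) were higher (list adjusted p = 0.00283, and 0.317 with an estimated correlation). Cholesterol synthesis fell in 11 of 18 genes (13 adjusted over the list alone), with PMVK (-2.47), HSD17B7 (-2.02) and MVD (-1.78) in front (adjusted p = 6.3e-05, and 0.0797 with an estimated correlation). The TCA cycle and oxidative phosphorylation list had 4 of 33 genes lower, such as CYC1 (-0.85) and NDUFV1 (-0.81), but 0 adjusted over the list alone (adjusted p = 0.458). Antioxidant and glutathione genes split into 7 higher and 7 lower of 22 (7 and 8 adjusted over the list alone). The red cell peroxiredoxin PRDX2 (2.26), HMOX1 (2.22) and GCLM (2.13) were up and NQO1 (-2.22) was down (mean 0.16, median -0.04, adjusted p = 0.406). Of day 11, 2 of 3 arrays lay above their median for NQO1, and of day 1, 2 of 3 for HMOX1. The weakest of these calls ended without 1 array. The call of CYC1 ended without any 1 of 11 arrays, as without day 1 replicate 2 (-0.69, adjusted p = 0.191). Also lost were those of NDUFV1 without day 11 replicate 1 (-0.57, adjusted p = 0.225), of HMOX1 without day 1 replicate 3 (1.87, adjusted p = 0.103) and of MVD without day 1 replicate 3 (-1.43, adjusted p = 0.0857).

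Signalling and stress lists were mixed on day 11 against day 1. Erythropoietin and cytokine signalling gave 8 higher and 10 lower of 26 (9 and 12 adjusted over the list alone). EPOR and the adaptor GAB1 (2.54) were up, and the interleukin 3 receptor chain IL3RA (-3.17) and the phosphatase PTPN6 (-2.48) were down. The mean of this list was -0.25 against an upward sign of the test (adjusted p = 0.954). Glucocorticoid induced genes gave 5 higher and 3 lower of 17 (the same adjusted over the list alone, adjusted p = 0.103). TXNIP (2.42) and TSC22D3 (1.92) were up, ALOX5AP (-3.40) was down and the dexamethasone marker FKBP5 stood at 0.27. Immediate early and stress genes gave 5 higher and 4 lower of 20 (6 and 4 adjusted over the list alone, adjusted p = 0.0636). ATF3 (4.18) and DUSP1 (2.31) were up, and the inflammatory genes TNFAIP3 (-3.99) and CXCL8 (-2.25) were down. Interferon response genes fell in 8 of 20 cases and rose in 1 (10 and 1 adjusted over the list alone). MX2 (-4.56, at least 4.24-fold), PSMB9 (-4.13, at least 7.1-fold) and XAF1 (-3.60) were lower and IFI27 (2.54) was higher (list adjusted p = 0.0105, and 0.233 with an estimated correlation). Heat shock and unfolded protein genes gave 4 in each direction of 21 (the same adjusted over the list alone). BAG3 (2.67) and DDIT3 (1.84) were up and PDIA4 (-0.79) was down (mean 0.07, median -0.15 and a downward sign of the test, adjusted p = 0.949). Of day 11, 1 of 3 arrays lay above its median for XAF1 and 2 of 3 for ALOX5AP and IL3RA, and of day 1, 1 of 3 for IFI27 and 2 of 3 for ATF3 and BAG3. IL3RA stood at -2.33 (adjusted p = 0.0815) and PDIA4 at -0.67 (adjusted p = 0.0536) without day 11 replicate 1. Of the 116 calls of named genes in this comparison, 103 held with any 1 array left out and 104 under both other scalings.

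**Figure D2:**
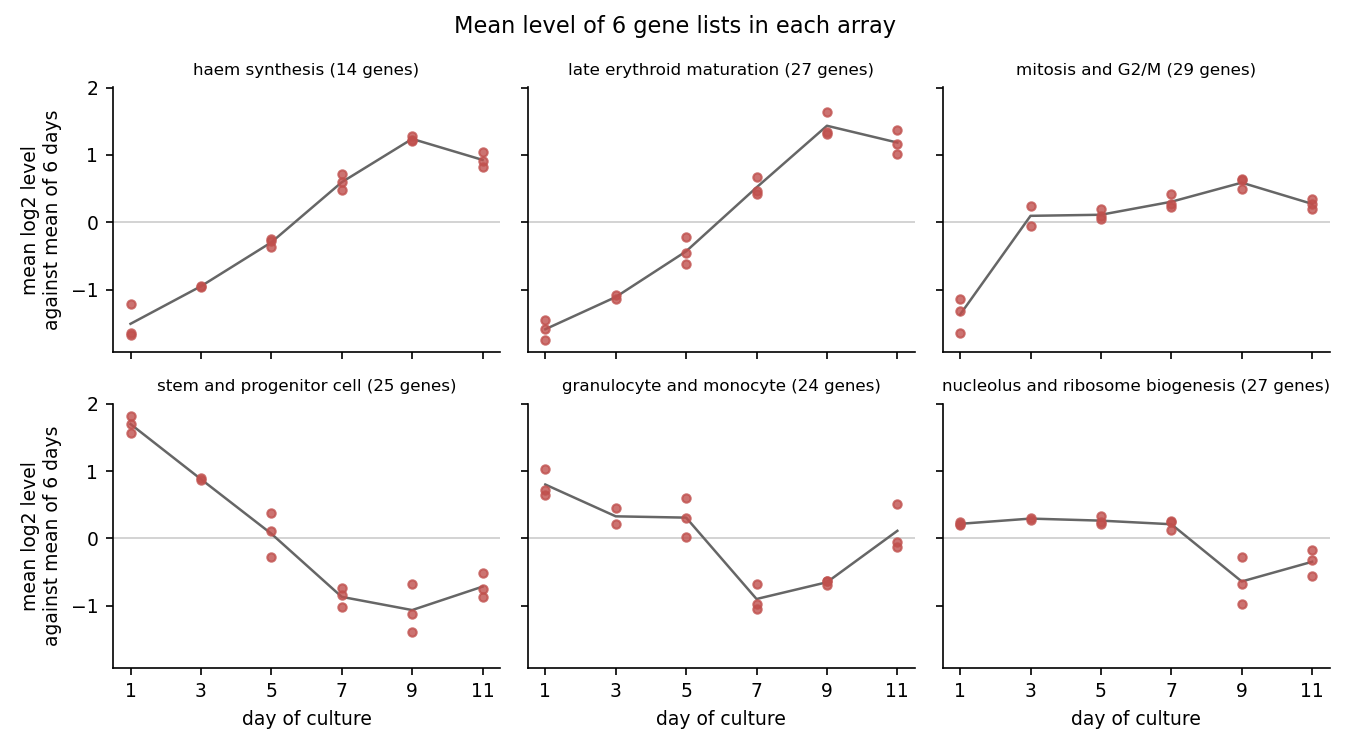
Mean log2 level of 6 gene lists in each array (points) against the day of culture, relative to the mean of the 6 days, with the mean of each day as a line (n = 3 arrays a day, 2 on day 3). Haem synthesis and late maturation climb to day 9, mitosis steps up by day 3, and the nucleolus list drops on day 9.

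From day 1 to day 3 genes of mitosis and globin genes rose. Of the 29 mitosis and G2/M genes 23 rose (29 adjusted over the list alone), among them KIF20A (2.71 ± 0.41), DLGAP5 (2.58 ± 0.22), cyclin B (CCNB1, 2.49 ± 0.29) and MKI67 (2.19 ± 0.30). BIRC5 stood at 0.50 and CCNA2 at 0.46 (list mean 1.47, adjusted p = 3.13e-46, and 0.00179 with an estimated correlation). AHSP rose by 4.89 ± 0.64 (29.7-fold, adjusted p = 6.42e-05), HBM by 2.03 (at least 2.65-fold) and HBB by 1.74. In all 5 of 7 globin genes rose (5 adjusted over the list alone, list adjusted p = 2.51e-09, and 0.0111 with an estimated correlation). The membrane skeleton gene ADD2 (4.08 ± 0.41, 17-fold), the Rh-associated RHAG (3.08) and EPB42 (2.70) rose and the adhesion protein SEMA7A (-1.80) fell. In the membrane list 8 of 24 genes were higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 2.65e-09, and 0.0215 with an estimated correlation). Haem synthesis had 3 of 14 genes higher (8, with 2 lower, adjusted over the list alone), among them PPOX (1.36) and FECH (1.30), with adjusted p = 1.9e-05, and 0.0222 with an estimated correlation.

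Immediate early and stress genes fell over the same step. Of 20 immediate early and stress genes 6 fell (9 adjusted over the list alone), led by CXCL8 (-4.65), the NF-kappaB regulators TNFAIP3 (-4.55) and NFKBIA (-2.48) and IER3 (-2.89) (adjusted p = 4.88e-10, and 0.0205 with an estimated correlation). The chemokine CXCL1 fell at least 12.6-fold, and the cytokines IL32 and EBI3 at least 7.97-fold and 18.5-fold. LIMCH1 (-5.96 ± 0.91) and the pseudogene WFDC21P (-5.22 ± 1.01) also fell (adjusted p from 0.000316 to 0.00349). Glucocorticoid induced genes fell in 3 of 17 cases (5 adjusted over the list alone), TSC22D3 (-1.56), KLF9 (-1.40) and DDIT4 (-0.97), with FKBP5 at -0.07 (adjusted p = 6.22e-05, and 0.0378 with an estimated correlation). The feedback inhibitors SOCS1 (-2.15), SOCS3 (-1.76) and CISH (-1.39) fell and EPOR (1.60) rose. Their cytokine signalling list had no call (2 higher and 4 lower of 26, 2 and 6 adjusted over the list alone, adjusted p = 0.0659). The macrophage list had 3 of 15 lower (4 adjusted over the list alone), including CD163 (-4.15) and the mannose receptor MRC1 (-2.67), with adjusted p = 2.06e-05, and 0.059 with an estimated correlation. The other largest fitted rises were SLC10A4 (4.69 ± 0.84), the noncoding RNA PELP1-DT (at least 5.06-fold) and SH3TC2 (at least 1.94-fold), with adjusted p from 0.000705 to 0.00177. The bounds of PELP1-DT and SH3TC2 do not rank them above genes bright on all arrays of day 1, such as RHAG (3.08).

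The list test also passed erythroid transcription factors (mean 0.50, 4 of 21 higher), late maturation (0.48, 6 of 27 higher) and the TCA cycle and oxidative phosphorylation (0.09, 0 of 33 called) upward. Downward it passed stem and progenitor cell (-0.82, 1 of 25 lower), lymphoid (-1.17, 1 of 17 lower), ribosomal proteins (-0.16, 0 of 27), cholesterol synthesis (-0.44, 0 of 18) and interferon response (-0.78, 1 of 20 lower). Over the list alone 7, 9 and 0 were higher in the former, with 1 late maturation gene lower, and 1, 4, 0, 2 and 1 lower in the latter. For these 8 lists adjusted p was 6.43e-05, 7.25e-05, 0.0429, 0.0005, 0.00745, 0.0294, 0.00312 and 0.0135, and 0.12, 0.135, 0.434, 0.105, 0.233, 0.687, 0.194 and 0.233 with an estimated correlation. Of 15 list calls at this step 11 held with any 1 array left out and 13 under both other scalings. On day 1, 1 of 3 arrays lay above its median for ADD2 and 2 of 3 for AHSP, EPB42 and SLC10A4, and on day 3, 1 of 2 for LIMCH1, WFDC21P and CD163.

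Between days 1 and 3, 260 genes rose and 257 fell (limma). Day 3 replicate 3, the array with the high 3' to 5' ratio, is 1 of only 2 on day 3. Without it 140 rose and 119 fell. Without day 3 replicate 1 the falls numbered 408. Without day 1 replicate 1, 2 or 3 the falls numbered 153, 101 and 134, with 156 rises without day 1 replicate 3. Of 51 calls of named genes, 30 held with any 1 array left out and 35 under both other scalings. Those lost without day 3 replicate 3 include CXCL1 (-4.73, adjusted p = 0.0574), WFDC21P (-3.86, adjusted p = 0.114), SH3TC2 (3.31, adjusted p = 0.0595), PPOX (1.31, adjusted p = 0.0599), KLF9 (-1.17, adjusted p = 0.209), DDIT4 (-0.91, adjusted p = 0.192) and CD163 (-3.92, adjusted p = 0.0724). FECH (0.89, adjusted p = 0.0767) and SOCS3 (-1.55, adjusted p = 0.0945) were lost without day 3 replicate 1, and MRC1 (-1.90, adjusted p = 0.136) without day 1 replicate 1.

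Few genes passed the test between days 3 and 5. SLC4A1 rose by 3.63 ± 0.50 (12.4-fold, adjusted p = 0.000568), DOCK9, an exchange factor of Cdc42, by 3.01 ± 0.39 (8.07-fold, adjusted p = 0.000299) and TRIM10, an erythroid ubiquitin ligase, by 2.94 ± 0.49 (7.7-fold, adjusted p = 0.00552), and these calls held with any 1 array left out. MYZAP rose at least 2.05-fold and the pseudogene OR7E12P by 2.87 (adjusted p = 0.0184 and 0.0405). PROM1 (-4.13 ± 0.86, 17.5-fold), the serotonin receptor HTR2B (-3.35), the noncoding RNA RUNX1-IT1 (-2.75), the pseudogene RPS16P5 (-2.64) and PHGDH (-2.57), which starts serine synthesis, fell (adjusted p from 0.009 to 0.0468). HBB stood at 0.35 ± 0.23 (adjusted p = 0.64). Of 27 late maturation genes 4 rose (12 adjusted over the list alone), with HEMGN (2.18) and MXI1 (1.51) after TRIM10. Of 14 haem synthesis genes 1, FAM210B (1.12), rose (8 adjusted over the list alone), and of 24 membrane genes 1, SLC4A1, rose (10 adjusted over the list alone). The lists' adjusted p was 1.48e-12, 7.75e-09 and 5.05e-08, and 0.0193, 0.00831 and 0.0301 with an estimated correlation.

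The list test also passed globins (mean 0.64), antioxidant and glutathione (0.15), glucocorticoid induced (0.16) and immediate early and stress (0.40) upward with 0 members called. Downward it passed stem and progenitor cell (-0.81, with PROM1 the only 1 of 25 called), mast cell (-0.50), lymphoid (-0.87), macrophage (-0.57), glycolysis (-0.31), cholesterol synthesis (-0.34) and interferon response (-0.48), the last 6 with 0 members called. Over the list alone 2, 3, 2 and 3 were higher and 0, 1, 1 and 1 lower in the former, and 2, 1, 0, 2, 0, 0 and 1 lower in the latter. For these 11 lists adjusted p was 0.0221, 0.0476, 0.0294, 0.00802, 0.0135, 0.0382, 0.0254, 0.0226, 0.0135, 0.00124 and 0.0495. With an estimated correlation it was 0.233, 0.278, 0.233, 0.251, 0.233, 0.341, 0.309, 0.289, 0.388, 0.153 and 0.326. Of 14 list calls at this step 4 held with any 1 array left out and 9 under both other scalings. On day 5, 1 of 3 arrays lay above its median for RUNX1-IT1 and 2 of 3 for PROM1 and HTR2B, and on day 3, 1 of 2 for OR7E12P.

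In all, 30 genes rose and 17 fell between days 3 and 5, a share of 63.8% higher, against 78.0% under quantile normalization and 78.6% with equal medians, which moved the median change of all genes by 0.14. These counts hang on the 2 arrays of day 3. In detail, 459 rose and 201 fell without day 3 replicate 1, and 12 rose and 3 fell without day 3 replicate 3, the array with the high 3' to 5' ratio. With 1 of the 3 arrays of day 5 left out they ranged from 17 to 19 rises and 6 to 10 falls. Of 14 named calls 3 held with any 1 array left out and 6 under both other scalings. Apart from SLC4A1, DOCK9 and TRIM10, the named calls ended without day 3 replicate 3, as for PROM1 (-4.01, adjusted p = 0.399), PHGDH (-1.70, adjusted p = 0.472) and HEMGN (1.40, adjusted p = 0.284). The same held for MXI1 (1.06, adjusted p = 0.564), MYZAP (2.86, adjusted p = 0.245), OR7E12P (1.63, adjusted p = 0.948), RUNX1-IT1 (-2.36, adjusted p = 0.67), RPS16P5 (-2.57, adjusted p = 0.434) and FAM210B (1.06, adjusted p = 0.284). HTR2B lost its call without any 1 of 14 arrays, as without day 5 replicate 1 (-2.27, adjusted p = 0.11).

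Red cell membrane, haem and late maturation genes rose from day 5 to day 7, and granulocyte genes fell. Acetylcholinesterase (ACHE), a red cell surface enzyme, rose at least 4.51-fold, AQP1 by 4.64 ± 0.60 (24.9-fold), SLC4A1 by 3.40 ± 0.45 (10.6-fold), the lipid transporter ABCG1 by 3.36 ± 0.52 (10.2-fold) and HTR2B by 3.31 ± 0.65 (adjusted p from 0.000121 to 0.00392). Haem synthesis rose in 8 of 14 genes (11, with 1 lower, adjusted over the list alone), led by ALAS2 (2.89), ALAD (1.69) and FAM210B (1.41). Late maturation rose in 11 of 27 (16 adjusted over the list alone), led by TRIM10 (2.88). Membrane genes rose in 10 of 24 (13 adjusted over the list alone), including EPB42 (2.23) and the glucose transporter SLC2A1 (1.90), and transcription factors rose in 6 of 21 (9 adjusted over the list alone), including SOX6 (2.55) and E2F2 (1.92). Their adjusted p was 6.38e-14, 6.22e-18, 5.84e-16 and 1.62e-09, and 0.00179, 0.00871, 0.00797 and 0.029 with an estimated correlation. HBM rose by 2.91, the only 1 of 7 globin genes called (1 adjusted over the list alone). HBB stood at 0.35 (list adjusted p = 0.000138, and 0.059 with an estimated correlation).

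Granulocyte and monocyte genes fell in 5 of 24 cases (9 adjusted over the list alone). These include myeloperoxidase (MPO, -2.87), CST7 (-2.60), the integrin ITGAM (-2.09) and lysozyme (LYZ, -1.67), with adjusted p = 1.48e-05, and 0.0205 with an estimated correlation. Mast cell genes fell in 3 of 15 cases (5 adjusted over the list alone), HDC (-2.10), the carboxypeptidase CPA3 (-2.09) and the IgE receptor chain FCER1A (-1.96), with adjusted p = 0.000385, and 0.146 with an estimated correlation. Stem and progenitor genes fell in 8 of 25 cases and rose in 2 (11 and 2 adjusted over the list alone). SPINK2 fell at least 1.72-fold, CD38 at least 4.9-fold, GATA2 (-2.14) and the growth factor ANGPT1 (-2.45) were lower, and BEX1 rose by 1.77 (list adjusted p = 6.22e-05, and 0.0616 with an estimated correlation). POU2AF1, a B cell coactivator, CD300LF, a receptor of myeloid cells, and MTARC1, a mitochondrial reductase, fell at least 3.37-fold, 2.83-fold and 3.74-fold, and the surface protein CD48 fell by 3.46 (adjusted p from 0.00538 to 0.0467). MYC (-1.46) and SOCS1 (-1.88) also fell. The list test also passed megakaryocyte and platelet (mean 0.48, 2 higher and 1 lower of 19), mitosis and G2/M (0.19, 1 of 29 higher) and ribosomal proteins (0.09, 0 of 27 called) upward. Over the list alone 4, 1 and 0 were higher and 1, 0 and 0 lower. Adjusted p was 0.0162, 0.000822 and 0.0212, and 0.331, 0.295 and 0.679 with an estimated correlation. Of 11 list calls at this step 9 held with any 1 array left out and 11 under both other scalings. On day 5, 2 of 3 arrays lay above their median for AQP1 and HTR2B, and on day 7, 1 of 3 for CD48 and ITGAM and 2 of 3 for CST7.

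In all, 216 genes rose and 308 fell between days 5 and 7. Without 1 array the counts fell to 129 and 140 (day 5 replicate 1), 124 and 145 (day 5 replicate 3), 118 and 195 (day 7 replicate 1) and 87 and 118 (day 7 replicate 2). Of 49 named calls 24 held with any 1 array left out and 33 under both other scalings. Lost were those of CD300LF (-3.27, adjusted p = 0.0664), CD48 (-2.55, adjusted p = 0.0576), MTARC1 (-3.04, adjusted p = 0.216), SOX6 (2.21, adjusted p = 0.0692), CST7 (-1.92, adjusted p = 0.192), FCER1A (-1.32, adjusted p = 0.0694) and MYC (-1.28, adjusted p = 0.143) without day 7 replicate 2. Also lost were those of POU2AF1 (-2.96, adjusted p = 0.122), CD38 (-2.45, adjusted p = 0.118) and ITGAM (-1.71, adjusted p = 0.234) without day 5 replicate 1. The calls of ALAS2 (2.37, adjusted p = 0.0704) and HDC (-1.85, adjusted p = 0.13) ended without day 5 replicate 3 and that of MPO (-2.35, adjusted p = 0.0767) without day 7 replicate 1.

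From day 7 to day 9 genes that build ribosomes fell together. Of 27 genes of the nucleolus and ribosome biogenesis 17 fell (21 adjusted over the list alone), by a mean of 0.85 on the log2 scale, among them UTP20 (-1.61 ± 0.42), the polymerase I and III subunit POLR1C (-1.46 ± 0.23), RRS1 (-1.45 ± 0.27) and PES1 (-1.44 ± 0.33). NPM1 (-0.15) and GAR1 (-0.53) did not pass (list adjusted p = 5.6e-17, and 0.033 with an estimated correlation). In the list of cyclin D, CDK inhibitors and the MYC network CDKN2B (3.49), cyclin G2 (CCNG2, 2.14), BTG1 (1.58) and CDKN1B (1.34) were higher and CDK6 (-1.28) lower. This list had 5 higher and 1 lower of 23 (7 and 1 adjusted over the list alone, adjusted p = 0.000457, and 0.0309 with an estimated correlation). Late maturation rose in 12 of 27 genes (20 adjusted over the list alone), such as UBE2H (2.18) and PDZK1IP1 (2.51), and haem synthesis in 4 of 14 (5 adjusted over the list alone), such as the mitochondrial carrier SLC25A39 (1.29), with adjusted p = 3.54e-16 and 2.3e-06, and 0.0109 and 0.0175 with an estimated correlation. Membrane genes rose in 4 of 24 cases (8 adjusted over the list alone), including the urea transporter SLC14A1 (2.41) and dematin (DMTN, 1.51). Transcription factors rose in 7 of 21 (10, with 1 lower, adjusted over the list alone), including SOX6 (1.92) and NFE2 (1.19), with adjusted p = 1.66e-06 and 8.03e-07, and 0.052 and 0.059 with an estimated correlation.

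GDF15 rose by 4.56 ± 0.54 on day 9 against day 7 (23.5-fold, adjusted p = 2.36e-05), the ABC transporter pseudogene ABCC13 by 4.65 ± 0.72 (25.2-fold), arginase ARG1 at least 8.45-fold, the phosphatase PTPRH by 3.79 ± 0.86 and PIK3IP1, an inhibitor of PI3 kinase, at least 2.85-fold (adjusted p from 0.000167 to 0.0089). The largest fitted falls were those of LRP8-DT (at least 1.6-fold), KHDC1 (at least 2.05-fold), the class II pseudogene HLA-DRB6 (at least 3.6-fold), the meiotic cyclin CCNA1 (at least 2.66-fold) and the nucleotide receptor P2RY14 (at least 1.95-fold), with adjusted p from 0.000156 to 0.0455. As bounds, these do not rank them above falls of genes bright on all arrays of day 9, such as HK2 (-1.85). Glycolysis fell in 6 of 20 genes (10 adjusted over the list alone), with HK2 (-1.85) and ENO1 (-1.37) in front (adjusted p = 0.000178, and 0.233 with an estimated correlation). Glucocorticoid induced genes gave 4 higher and 1 lower of 17 (the same adjusted over the list alone), with KLF9 (2.46), TSC22D3 (2.30) and TXNIP (1.95) up and ALOX5AP (-2.61) down (adjusted p = 0.00124, and 0.0797 with an estimated correlation). Immediate early genes gave 3 higher of 20 (6 adjusted over the list alone), ATF3 (2.42), DUSP1 (1.29) and KLF6 (1.11) (adjusted p = 0.000189, and 0.122 with an estimated correlation). In the heat shock and unfolded protein list DDIT3 (2.17) and XBP1 (0.83) rose and the chaperonin HSPE1 (-1.15) fell. It had 2 called in each direction of 21 (2 and 10 adjusted over the list alone, adjusted p = 0.0177, and 0.297 with an estimated correlation). This call was lost without day 7 replicate 2 (mean -0.17, adjusted p = 0.0917). Mitosis and G2/M rose as a list, by a mean of 0.28 with 0 of 29 called or adjusted over the list alone (adjusted p = 0.000906, and 0.295 with an estimated correlation). The list test also passed globins (0.52, 0 of 7 called), iron uptake (0.25, 1 of 15 higher), megakaryocyte and platelet (0.45, 0 of 19 called), cholesterol synthesis (0.22, 2 of 18 higher) and cytokine signalling (0.27, 3 higher and 4 lower of 26) upward and the TCA cycle and oxidative phosphorylation (-0.20, 0 of 33 called) downward. Over the list alone 2, 2, 0, 2, 6 and 0 were higher and 0, 0, 0, 0, 4 and 0 lower. For these 6 lists adjusted p was 0.0433, 0.00722, 0.0277, 0.0252, 0.0214 and 0.00477, and 0.295, 0.225, 0.363, 0.3, 0.0637 and 0.309 with an estimated correlation. Of 17 list calls at this step 13 held with any 1 array left out and 13 under both other scalings. On day 7, 1 of 3 arrays lay above its median for ABCC13, PTPRH and CDKN2B, and on day 9, 1 of 3 for ALOX5AP. With the other arrays of day 7 raised to their median, ABCC13 rose 9.05-fold and PTPRH 3.87-fold.

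In all, 472 genes rose and 502 fell from day 7 to day 9, a share of 48.5% higher that became 85.0% (125 and 22 genes) once the medians of all arrays were set equal. Without 1 array the counts were 254 and 205 (day 7 replicate 1), 265 and 216 (day 7 replicate 3), 161 and 107 (day 9 replicate 2) and 272 and 307 (day 9 replicate 3). Of 50 named calls 25 held with any 1 array left out and 21 under both other scalings. Lost without day 9 replicate 2 were those of P2RY14 (-2.01, adjusted p = 0.16), KHDC1 (-2.72, adjusted p = 0.205), UTP20 (-1.61, adjusted p = 0.0879), PES1 (-1.11, adjusted p = 0.0982) and PDZK1IP1 (2.40, adjusted p = 0.0944). The same held for SOX6 (1.61, adjusted p = 0.205), NFE2 (0.99, adjusted p = 0.102) and SLC14A1 (2.15, adjusted p = 0.0639). Without day 7 replicate 3 those of PTPRH (3.14, adjusted p = 0.0643), CCNA1 (-2.56, adjusted p = 0.102) and DUSP1 (1.17, adjusted p = 0.0579) were lost. Without day 7 replicate 1 those of CDKN2B (2.83, adjusted p = 0.173) and XBP1 (0.71, adjusted p = 0.129) and without day 9 replicate 3 that of ALOX5AP (-1.65, adjusted p = 0.101) were lost.

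From day 9 to day 11 the red cell lists stopped climbing. Haem synthesis fell as a list, by a mean of 0.31 over 14 genes, 0 of them called by limma or adjusted over the list alone (adjusted p = 6.27e-05, and 0.0301 with an estimated correlation). Mitosis genes (mean -0.32), erythroid transcription factors (mean -0.28), late maturation genes (mean -0.25) and membrane genes (mean -0.25) fell as lists, with 0 members called of 29, 21, 27 and 24 and 0, 2, 1 and 0 lower adjusted over the list alone. Their adjusted p was 2.97e-07, 0.000457, 0.00227 and 0.00368, and 0.122, 0.166, 0.233 and 0.221 with an estimated correlation. Granulocyte and monocyte genes rose by a mean of 0.76, with 1 of 24 called, LYZ (1.60), from 890 ± 333 to 2668 ± 767, and 3 adjusted over the list alone (adjusted p = 0.00154, and 0.0601 with an estimated correlation). Mast cell genes rose by a mean of 0.77, with 1 of 15 called, CPA3 (1.71), and 4 higher and 1 lower adjusted over the list alone (adjusted p = 0.0263, and 0.317 with an estimated correlation). Immediate early genes rose by a mean of 0.88, with 0 of 20 called and 7 adjusted over the list alone (adjusted p = 2.3e-06, and 0.059 with an estimated correlation). Macrophage and antigen presentation (mean 0.58) and megakaryocyte and platelet genes (mean 0.50) also rose as lists and cholesterol synthesis (mean -0.14) fell, with 0 of 15, 19 and 18 called and 6 and 3 higher and 1 lower adjusted over the list alone. Their adjusted p was 0.0226, 0.0449 and 0.0334, and 0.289, 0.413 and 0.317 with an estimated correlation. Of 17 list calls at this step 5 held with any 1 array left out and 10 under both other scalings. CLEC2B, a C-type lectin of leukocytes, rose by 2.90 ± 0.31 (7.46-fold, adjusted p = 3.3e-05), P2RY14 at least 3.22-fold and UBTD2 by 3.20 ± 0.54 (9.18-fold, and 2.81-fold with the 2 of 3 arrays of day 9 below their median raised to it). EHD2 rose by 2.57 ± 0.48 and HLA-DRB6 at least 2.6-fold (these last 4 genes at adjusted p from 0.0101 to 0.0365), and the glycolytic HK2 by 1.42 (adjusted p = 0.00842).

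In the main fit 18 genes rose and 0 fell between days 9 and 11 (limma), against 1022 higher and 563 lower at an unadjusted p below 0.05. With the replicate number as a block in the model, 64 rose and 11 fell. Day 11 replicate 1, the array with the high median signal, is 1 of 3 on day 11. Setting all medians equal moved the median change of all genes by -0.42 and left 1 gene higher and 1 lower, a share of 50.0% higher against 100% as deposited. Quantile normalization moved the median by -0.12 and gave 85.7%. Heat shock genes (0.37), nucleolus genes (0.29), glycolysis (0.31), glucocorticoid induced genes (0.41), ribosomal proteins (0.16) and stem cell genes (0.35) also passed the list test upward. For these lists adjusted p was 3.14e-06, 0.000546, 0.00274, 0.0254, 0.0135 and 0.0395, and 0.059, 0.317, 0.317, 0.228, 0.679 and 0.309 with an estimated correlation. With members called higher numbering 0, 0, 1, 0, 0 and 0, and 3, 0, 6, 2, 0 and 2 higher and 0, 0, 1, 0, 0 and 0 lower adjusted over the list alone, their means turned to -0.05, -0.13, -0.11, -0.01, -0.26 and -0.07 with equal medians. Without 1 array the rises numbered 40 and 30 (day 9 replicates 1 and 3), 4 (day 9 replicate 2), 32 (day 11 replicate 1), 7 (day 11 replicate 2) and 2 (day 11 replicate 3). The falls numbered 7 (day 9 replicate 1), 6 (day 11 replicate 1), 4 and 3 (day 3 replicates 1 and 3) and 1 (day 9 replicate 2 or day 11 replicate 2). CLEC2B alone of the 8 named genes kept its call without any 1 array and under both scalings. Without day 11 replicate 3 adjusted p was 0.244 for P2RY14, 0.103 for UBTD2, 0.188 for EHD2, 0.0947 for HLA-DRB6 and HK2, 0.22 for LYZ and 0.204 for CPA3. It was 0.0577 for the granulocyte list (mean 0.57), 0.352 for the mast cell list (mean 0.36) and 0.0977 for the membrane list (mean -0.12). Without day 9 replicate 2 it was 0.124 for late maturation (mean -0.15).

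**Figure D3:**
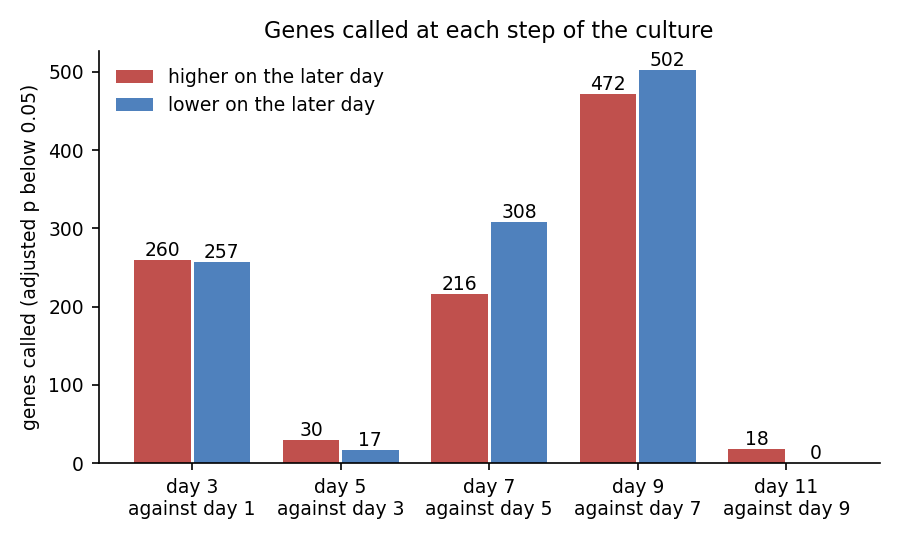
Number of genes called higher (red) or lower (blue) on the later day at each step between neighbouring days, at an adjusted p below 0.05 over 15619 genes (n = 3 arrays a day, 2 on day 3). The step from day 7 to day 9 has 472 and 502, and the step from day 9 to day 11 has 18 and 0.

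Some genes lay outside both ends of the culture in the mean of days 5 and 7, which was not compared with days 3 and 9. TUBB2B, a neural beta tubulin, lay 5.23 ± 0.47 above day 1 and 1.86 ± 0.47 above day 11 in the mean of days 5 and 7, the neuropeptide galanin (GAL) 3.06 and 1.72. By the same measure CCNA1 lay 1.83 and 3.63 above, TRIM29 2.56 (at least 3.45-fold) and 2.45 and the noncoding RNA RYR3-DT 3.01 (at least 2.76-fold) and 3.36 (at least 2.58-fold). IRAK2, a kinase of interleukin 1 signalling, lay 3.53 ± 0.34 below day 1 and 4.03 ± 0.34 below day 11 (differences of -3.53 and -4.03). PIK3IP1 stood at -4.51 and -3.31, the interferon induced GBP4 at -3.69 and -2.85, DAPK1-IT1 at -3.57 and -3.46 and SBF2-AS1 at -2.93 (at least 1.19-fold) and -2.91 (at least 1.17-fold). Of day 1, 1 of 3 arrays lay above its median for TUBB2B and 2 of 3 for GAL, and of day 11, 1 of 3 for CCNA1 and TRIM29. Of days 5 and 7, 5 of 6 arrays lay above their median for IRAK2, 2 of 6 for GBP4 and 1 of 6 for PIK3IP1 and DAPK1-IT1. With the arrays below their median raised to it, the middle over the end was 17.1-fold for TUBB2B and 7.41-fold for GAL (day 1) and 3.13-fold for CCNA1 and 2.56-fold for TRIM29 (day 11). The ends over the middle (day 1, then day 11) were then 11.5-fold and 16.3-fold for IRAK2, 9.3-fold and 4.05-fold for PIK3IP1, 8.05-fold and 4.51-fold for GBP4 and 4.53-fold and 4.19-fold for DAPK1-IT1. In all, 104 genes were higher and 203 lower than at both ends (limma, adjusted p below 0.05 in both comparisons, from 1.44e-08 to 0.0348 for the genes named). Higher genes numbered 61 without day 5 replicate 2, 60 without day 7 replicate 3, 41 without day 11 replicate 1 and 68 without day 11 replicate 2. Lower genes numbered 135 without day 11 replicate 1, and equal medians left 31 and 28.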

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

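Of the tests in this part, only that on the share of erythroid cells was chosen after its result was seen. The array without a day has an AHSP signal of 1054.6, above the 6.9 to 171.8 of day 1, and is in no comparison. On the leading principal component it lay at -62.75, between the 2 arrays of day 3 (-71.46 and -43.71). Day 3 replicate 3 has a mean 3' over 5' log2 ratio of 7.14 in its control probe sets, which serve no gene comparison, against 1.59 to 4.28 on the other arrays.

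The distance of day 3 replicate 3 from day 3 replicate 1 was weighed because these are the only arrays of that day. Across genes the difference had r = -0.064 with the change from day 1 to day 5. This lies inside the bounds of -0.1 and 0.1 set as speaking against another stage of the culture. On the leading principal component, however, replicate 3 lay at -71.46 and replicate 1 at -43.71, with day 1 from -115.58 to -104.21. Another stage therefore stays open, as the r compares 2 single arrays. A 3' bias of the RNA stays open, since r was 0.267 with the slope on the 3' to 5' ratio within the other days, between the bounds of 0.1 and 0.3. Genes are not independent replicates in these correlations. No biological explanation was tested beyond the stage of the culture.

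The fall of red cell lists from day 9 to day 11 was weighed on the haem synthesis list, whose mean change was -0.31. It was -0.37 without day 11 replicate 1 and -0.315 with the 3' to 5' ratio in the model, both past the threshold of camera. This argues against that array, and against a 3' bias with the slope seen within days, as the whole cause. The widest spread of the ratio within a day was that of day 3 (1.96 and 7.14). Day 9 (2.53 to 2.84) and day 11 (3.02 to 3.29) did not overlap in it, so a bias of another slope stays open. A lower share of erythroid cells would raise the markers of other cell types alike. Over 7 bright members the granulocyte and monocyte list rose by 1.25 against 0.271 for the other lists, 4.18 standard errors apart over genes, which are not independent, but 1.77 over arrays. The mast cell, megakaryocyte and macrophage lists lay 0.3, -0.67 and -1.35 standard errors from the others over genes and 0.41, -0.3 and -2.22 over arrays. Over all members these 4 lists rose by 0.763, 0.773, 0.502 and 0.584, and the lymphoid list stood at -0.081. No list with 5 or more bright members lay over 2 standard errors from the others by both measures, so a lower share of erythroid cells stays open, as does a growth of the granulocyte and monocyte share. The step of the culture itself, from day 9 to day 11, may be a candidate explanation and was not tested apart from these.

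The fall of the nucleolus and ribosome biogenesis list from day 7 to day 9 had a mean of -0.85. With the 3' to 5' ratio in the model it was -0.849, and over the 6 fits without 1 array of these days the value nearest to 0 was -0.684, both past the threshold of camera. Both values argue against a 3' bias with the slope seen within days, or a single array, as the whole cause. A change in the cells between these days may be behind it, as a hypothesis found and tested on the same data.

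Regroupings of the arrays were counted for each comparison with 3 arrays a side. For the 6 days, 1 of 100 regroupings, the real one, gave as many as 5575 genes and the highest other gave 1720, which argues against chance. For the middle days 2 of 100 gave as many as 307, the real one and another with 323. This share lies under the bound of 0.05, but a regrouping called more genes than the real days. That other regrouping gave 1 of its 6 middle labels to an array of days 5 and 7 and the rest to arrays of days 1 and 11. It thus nearly exchanged the middle and the ends, so real differences between days can enter its count. Another regrouping with 1 such middle label gave 43, and no other regrouping called a gene. How the remaining labels were spread was not compared. The 323 therefore cannot tell whether chance gives as many genes, and chance is neither shown nor excluded by it. For day 11 against day 1 (4197 genes, highest other 0), day 7 against day 5 (524, highest other 0), day 9 against day 7 (974, highest other 0) and day 11 against day 9 (18, highest other 2), the 10 splits are too few for a share under 0.05.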

How the results depend on the processing

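Chosen only after the data were seen were 16 times the pseudocount and leaving out both doubted arrays. The totals here leave out the estimated correlation, which is given below. Over all other alternatives 4476 of 4830 list values (92.7%) and 8940 of 9718 values of named genes (92%) kept their direction and their side of the threshold. Of the rest, 201 list values and 748 gene values lost their call, 50 and 14 gained one, 15 and 1 reversed, and 88 and 15 without a call changed sign. The cause of the differences below was not tested, except that fewer arrays or tested genes are part of some settings.

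Quantile normalization gave 9 genes lower on day 5 than on day 3 and 3 lower on day 11 than on day 9, and reversed cytosolic ribosomal proteins to -0.035 for day 11 against day 1 and -0.039 for day 11 against day 9. With equal medians 3190 genes differed among the days. That setting gave 823 genes higher on day 11 than on day 1, 66 higher and 95 lower on day 3 than on day 1, 11 and 3 on day 5 than on day 3, 71 and 97 on day 7 than on day 5, 125 and 22 on day 9 than on day 7, 1 and 1 on day 11 than on day 9, and 31 and 28 in the middle days. For day 11 against day 9 it reversed stem and progenitor cell (-0.072), nucleolus (-0.126), cytosolic ribosomal proteins (-0.264), glycolysis (-0.113), glucocorticoid induced (-0.006) and heat shock (-0.053).

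A pseudocount lowered 4-fold gave 8 genes lower on day 5 than on day 3. The filter at the 75th percentile gave 9 there and 3 lower on day 11 than on day 9. The mean of a gene's probe sets gave 153 lower on day 3 than on day 1, 18 higher and 11 lower on day 5 than on day 3, 180 lower on day 7 than on day 5 and 4 lower on day 11 than on day 9, and reversed SPRY1 to 0.078 for day 9 against day 7. It moved the uncalled PIEZO1 to 0.84 and MYB to 0.61 for day 11 against day 1. Without a trend 113 were higher and 1.1e2 lower (rounded to 2 digits) on day 3 than on day 1, 5 and 2 on day 5 than on day 3, 97 and 116 on day 7 than on day 5, 244 and 175 on day 9 than on day 7, 4 higher on day 11 than on day 9 and 47 higher in the middle days. Robust fitting gave 1 lower on day 11 than on day 9. The replicate block gave 64 higher and 11 lower on day 11 than on day 9. Departures of arrays from their day's mean were correlated to see whether replicate numbers pair. Of 40 pairs of arrays with the same number 11 had r over 0.1, with a median of 0.044 against -0.0245 for 80 pairs with different numbers. All 11 lay among days 5, 7, 9 and 11, where every pair with the same number had r from 0.049 to 0.268. Pairs with different numbers ranged there from -0.228 to 0.11. Same-number pairs with day 1 had -0.069 to 0.088. Departures of the 2 arrays of day 3 mirror each other, so their pairs add no separate evidence. Same-number pairs of days 9 and 11 had 0.268, 0.069 and 0.215. Not every array was most like its own number, 12 of 17 were. These values speak for pairing by number on days 5 to 11, but not on day 1. The title of the array without a day gives culture 3 where the other titles give the day, so it is no evidence on pairing. No title states the pairing outright, so what the numbers stand for stays open. The RNA quality covariate gave 11 lower on day 5 than on day 3, and 29 higher and 5 lower on day 11 than on day 9. With only the arrays of the 2 days in the fit, 98 were higher on day 3 than on day 1, 4 higher and 1 lower on day 5 than on day 3, and 10 higher and 3 lower on day 11 than on day 9. The estimated correlation left 26 list calls of 91.

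With 16 times the pseudocount 528 were lower on day 3 than on day 1 and 30 lower on day 5 than on day 3. With both doubted arrays out 136 were higher and 121 lower on day 3 than on day 1, 13 and 3 on day 5 than on day 3, 51 and 7 on day 11 than on day 9, and 63 higher in the middle days. That setting reversed TCA cycle for day 3 against day 1 to -0.015 and glucocorticoid induced for day 5 against day 3 to -0.018.

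Leaving out 1 array, where day 3 may be left with a lone array assumed to vary like the other days, the genes that differ among the days ranged from 4718 to 6241. Higher and lower genes ranged from 1290 to 1716 and 1929 to 2712 for day 11 against day 1, 140 to 268 and 101 to 408 for day 3 against day 1, 12 to 459 and 3 to 201 for day 5 against day 3, 87 to 283 and 118 to 355 for day 7 against day 5, 161 to 577 and 107 to 596 for day 9 against day 7, 2 to 40 and 0 to 7 for day 11 against day 9, and 41 to 144 and 135 to 234 for the middle days. List calls ranged from 81 to 93. Lists that reversed ranged from -0.015 (without day 3 replicate 3) to 0.201 for TCA cycle on day 3 against day 1, and from -0.018 (without day 3 replicate 3) to 0.332 for glucocorticoid induced on day 5 against day 3. Cytosolic ribosomal proteins ranged from -0.119 to 0.130 (without day 5 replicate 2) on day 5 against day 3. On day 7 against day 5 they ranged from -0.065 (without day 5 replicate 2) to 0.243, with -0.045 without day 7 replicate 2. The signal over background limits the genes given as bounds, whose fold depends on the pseudocount.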

Other observations

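The tests of the 2 lists below were planned after the values of some of their genes had been seen, and those genes were left out. Other members stand in the 26 fixed lists, which had been tested. The checks of list overlap, other steps and scalings were chosen only after the result was seen. Genes that cells switch on when amino acids run short rose from day 7 to day 9. Among them were SESN2 (2.99), which restrains mTORC1, the glutathione degrading enzyme CHAC1 (2.61), DDIT3 (2.17), the transcription factor CEBPB (2.09), the cysteine makers and importers CTH (1.72) and SLC7A11 (1.70), the tryptophanyl transfer RNA synthetase WARS1 (1.71), PSAT1 (1.36) of serine synthesis and asparagine synthetase ASNS (1.17), while ADM2 stood at -1.02. A list of 34 targets of ATF4, the transcription factor of that response, had 19 genes higher and 0 lower (limma) and a mean change of 1.183 (camera, p = 1.45e-26, and 0.000456 with an estimated correlation). GDF15, TRIB3, STC2, ASS1 and PHGDH, seen before, were not in it. The list's mean was 0.44 for day 7 against day 5 and -0.221 for day 11 against day 9. It was 1.159 under quantile normalization, 1.274 with equal medians, 0.978 to 1.321 without 1 array, and 1.12 over the 31 members in none of the 26 lists (camera, p = 1.02e-23, and 0.000411 with an estimated correlation). ATF4 activity may be a candidate explanation for this group, and haem shortage, amino acid use or medium age were not tested.

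Genes controlled by FOXO factors, which slow growth and favour autophagy, also rose from day 7 to day 9. Of 28 listed targets 12 were higher and 1 lower: the autophagy gene GABARAPL1 (2.26), CCNG2 (2.14), TXNIP (1.95) and SESN3 (1.64) rose, and ULK2 (-1.06) fell. The mean change was 0.717 (camera, p = 1.18e-11, and 0.00314 with an estimated correlation), 0.595 over the 13 members outside the 26 lists (camera, p = 0.00113, and 0.0152 with an estimated correlation), and 0.669 to 0.766 without 1 array. FOXO activity may be a candidate explanation, and 3 of the 28 are late maturation genes that red cell precursors raise in any case.

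In the array without a day HBB was at 12943.0 (3444.0 to 6823.0 on day 1), MKI67 at 1765.6 (524.0 to 750.4), PROM1 at 1581.1 (3927.9 to 6241.8), CD34 at 1053.9 (1208.2 to 1708.1) and SLC4A1 at 49.8 (7.2 to 68.6). Across genes, which are not independent replicates, its r was 0.9276 to 0.9401 with the arrays of day 1, 0.9623 and 0.9231 with those of day 3, 0.9191 to 0.9371 with day 5, 0.8959 to 0.9268 with day 7, 0.8645 to 0.8901 with day 9 and 0.8442 to 0.9088 with day 11. The 0.9623 was the highest r of all 153 pairs of arrays. Relative to the mean of the 6 days, its haem synthesis list stood at -0.838 and its late maturation list at -1.199. Day 3 had means of -0.95 and -1.11 there, and day 1 of -1.508 and -1.589. By these values the array lay nearest to day 3, but its day was not tested and it stays unassigned.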
